A study of Mus musculus with 9 samples.

How the data were processed

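Total RNA of mouse esophagus was hybridised to Agilent arrays with 2 colours, 1 array per sample, 9 in all. Per the labels, the sample was labelled with Cy5 and a universal mouse reference RNA with Cy3 on every array, with no dye swap, so dye effects of a probe stay in each ratio and drop out of differences between groups only where they are equal on the arrays compared. Per the labels' protocols, RNA was taken from esophageal tissue with a kit for fibrous tissue, while the cell type label names epithelium. The files hold, per the file headers, the mean intensity of each spot and the median intensity of its local background in each channel, without subtraction, as written by Agilent Feature Extraction 10.7.3.1. The submitters' processing notes name version 9.1 of that software. Per the file headers, the software also wrote processed intensities, with a background surface subtracted and dyes normalized within the array, and the log10 ratio of Cy5 over Cy3 made from them. The deposited value table of the series holds log2 ratios of Cy5 over Cy3 for 41267 probes. Each of its columns correlated with the log2 ratio of its own array at r of 0.992 or more, and its column medians lay between -0.212 and -0.0292. How the authors combined replicate spots and which centring they used are not given in the sources used here.

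Each file had 45018 spots, of which 1639 were controls, and 41174 probes remained. Spots marked as non-uniform or population outliers by the scanner software (119 to 171 per array) were left out, and no sample spot was saturated. Background was corrected by normexp on the mean and local background signals with an offset of 50, log ratios were normalized by loess within each array with control spots at weight 0, and no scaling between arrays was applied. Spots of 1 probe were averaged. Probes well above background in the sample channel on at least 2 of the 9 arrays were kept, 33761 in number, and each gene was read from its brightest probe, which gave 22626 gene names. Of the 41174 probes 26918 were named through their accession and 5899 through a symbol or synonym in a RefSeq table (assembly GRCm38.p6, used for names only), and 8357 kept the name in the file. Coordinates are those of the files, mouse build mm9. A fold against a group in which the probe was not well above background on any array is given as a lower bound, from the sample channel after loess and Aquantile, with each dim array set to the higher of its own value and the lowest signal of a probe well above background there. Such bounds are open to dye bias.

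Genes were tested with limma 3.58.1 in R 4.3.3, in 1 linear model over all 9 arrays with 3 genotypes, moderated by eBayes, with Benjamini-Hochberg adjustment in each comparison at 0.05. Gene lists were tested with camera at its preset correlation of 0.01, again with adjustment, over 28 lists with at least 5 measured genes each, and beside it with an estimated correlation and with fry. Camera compares a list with the other genes, while fry asks whether its genes move, on balance, in 1 direction. The groups, the lists, the tests, the alternatives and the rule for named genes were set before the data were examined. That rule names Trp63, the Cdx family and Vil1, the 10 genes that rose most and the 10 that fell most among those that passed, did not overlap between groups, were well above background on every array of the higher group and had a gene symbol, and from each list up to 2 passing members in each direction. Some genes that this rule names are not reported here and are left out of the test for single distant arrays, while the counts over all genes, lists and named calls include them. Where no member passed, the one with the lowest p could be given. Genes outside the rule are said to be picked after their values were seen, and the further list members given with a bare log2 difference were picked in the same way among those that passed.

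The fits were tested on simulated data with each gene's wild type mean and residual spread and 200 changed genes. Of genes changed by 1, 2 or 3 on the log2 scale, 70.1%, 92.5% and 100% were called for the knockout against wild type, 59.7%, 88.1% and 98.5% for the knockout with Cdx2 against the knockout, and 61.2%, 86.6% and 97.0% for the knockout with Cdx2 against wild type. With no change simulated, 0 genes were called in each of the 3 comparisons. The correlation and covariance of both comparisons with wild type were set against 50 simulations of unchanged groups that share the wild type arrays. Other background corrections, normalizations, filters, probe summaries, weights, variance priors, fits with fewer groups, the sample channel alone, the authors' table and the omission of each array were tried as alternatives. The sex of each mouse, read from Xist as 3 females and 1 male in wild type, 2 and 1 in the knockout and 1 and 1 in the knockout with Cdx2, was added as a covariate after the data were seen, and so was a scaling of the log ratios to 1 median absolute deviation per array. The latter was first run with a function for other data and was corrected before use. Lists for liver, exocrine pancreas, stomach lining and thymus were also added after the data were seen and enter no list test.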

Results

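Gene expression was measured in the esophagus of newborn mice (postnatal day 0) of 3 genotypes, on arrays with 2 colours. The transcription factor p63, encoded by Trp63, is a regulator of stratified squamous epithelium, and Cdx2 is a transcription factor of the intestinal epithelium. The groups were wild type mice (n = 4), p63 knockout mice (n = 3) and p63 knockout mice that also carried a Cdx2 transgene named for the villin promoter (n = 2). Each sample was labelled with Cy5 and set against 1 common reference RNA from 11 mouse cell lines, labelled with Cy3. Between 30038 and 33249 probes per array were well above background in the sample channel, and the median sample signal per array lay between 309 and 472 intensity units. Each genotype lay on a slide and in a scan of its own, so batch and genotype cannot be told apart in any comparison. The labels call the samples of a group biological replicates, and they number those with Cdx2 out of 3, of which 2 are in the series. One label of wild type replicate 4 named the knockout, while its title and genotype named wild type. Its Krt14 log2 ratio of 1.31 lay with the other wild type arrays. Its Nnt log2 ratio, picked after the values were seen, was -0.64 and lay with the knockout (-0.67 to -0.49). The other wild type arrays were at 0.01 to 0.07 for Nnt. What set this array apart in Nnt was not tested.

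The targeted genes were read first. The brightest Trp63 probe (mm9, chromosome 16, 25892012 to 25892071, 4526 bases into the transcript) had a mean log2 ratio of 3.71 ± 0.33 (SD, n = 4) in wild type, 2.73 ± 0.00 (SD, n = 3) in the knockout and 3.23 ± 0.20 (SD, n = 2) in the knockout with Cdx2. The knockout lay below all wild type arrays, and the difference of -0.98 (SE 0.17) did not pass in limma (adjusted p = 0.0742). In the sample channel alone it was -1.24 and passed (limma, adjusted p = 0.0144). The knockout with Cdx2 differed from wild type by -0.48 (SE 0.19; limma, adjusted p = 0.239). A Trp63 probe at 25865388 to 25866165 was dim, with log2 ratios from 0.16 to 0.73 in wild type, 0.72 to 0.83 in the knockout and 1.13 to 1.43 in the knockout with Cdx2. The third Trp63 probe was not well above background on any of the 9 arrays. Which part of the gene was deleted is not stated in the labels, and a probe outside that part checks nothing. The probes for Cdx1, Cdx2 and Cdx4 were not well above background on any of the 9 arrays. Whether the Cdx2 probe, 2014 bases into its transcript, reads the transcript of the transgene was not checked, so this does not show that the transgene was silent. The highest Cdx2 signal over background was 21.7 intensity units, in replicate 2 of the knockout with Cdx2. For Vil1, the gene of the villin promoter, no difference between the knockout with Cdx2 and the knockout passed (log2 difference -0.10, SE 0.65; limma, adjusted p = 0.968). With that SE, a 2-fold change either way is not excluded. The SE came from the spread within all groups of the 9 arrays, wild type included, where the brightest probe ranged from 0.43 to 3.05. On the arrays compared here it ranged from 1.56 to 1.96 in the knockout and was 1.44 and 1.99 with Cdx2. The highest log2 ratio of the Vil1 probes was in wild type replicate 1, at 3.05 for the brightest and 3.40 for the other.

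The comparison of p63 knockout with wild type asked which genes of the newborn esophagus depend on p63. Serpinb5, a serpin of epithelial cells, fell by 3.26 (SE 0.22) on the log2 scale in the knockout (n = 3) against wild type (n = 4), a fold of 9.56. Pkp1, a plaque protein of desmosomes, fell by 3.04 (SE 0.16), and Krt14, a keratin of basal cells, fell by 2.22 (SE 0.10). Sprr3, a precursor of the cornified envelope, fell by 2.59 (SE 0.18), and the keratin Krt6b fell by 2.40 (SE 0.15). Slc14a1, a urea transporter, rose by 2.30 (SE 0.19), the largest rise among the named genes. In limma, 74 of 22626 genes changed, 13 higher and 61 lower, and 47 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 1764 genes, against 1131 by chance.

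Among the genes that fell most were also Cysrt1 by 3.03 (SE 0.36), Tprg by 2.75 (SE 0.14), Lypd3 by 2.25 (SE 0.13) and the envelope gene Scel by 2.17 (SE 0.28). The Tprg probe lay on chromosome 16, as Trp63 does, at 25422306 to 25422365. Rises were smaller. Besides Slc14a1, the myeloid genes Ms4a3 and Ctsg rose by 1.77 (SE 0.21) and 1.74 (SE 0.17), and the pigment signal gene nonagouti (a) rose by 1.42 (SE 0.12). Calcb, Kcnj1 and the platelet receptor Clec1b rose by 1.38, 1.14 and 1.06. Igll1, Gad1 and Ascl3 rose by 0.79, 0.78 and 0.77. The limma adjusted p of these genes was at most 0.0469, and in each the arrays of the groups did not overlap. The rule for naming them required both passing and no overlap.

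**Figure D1:**
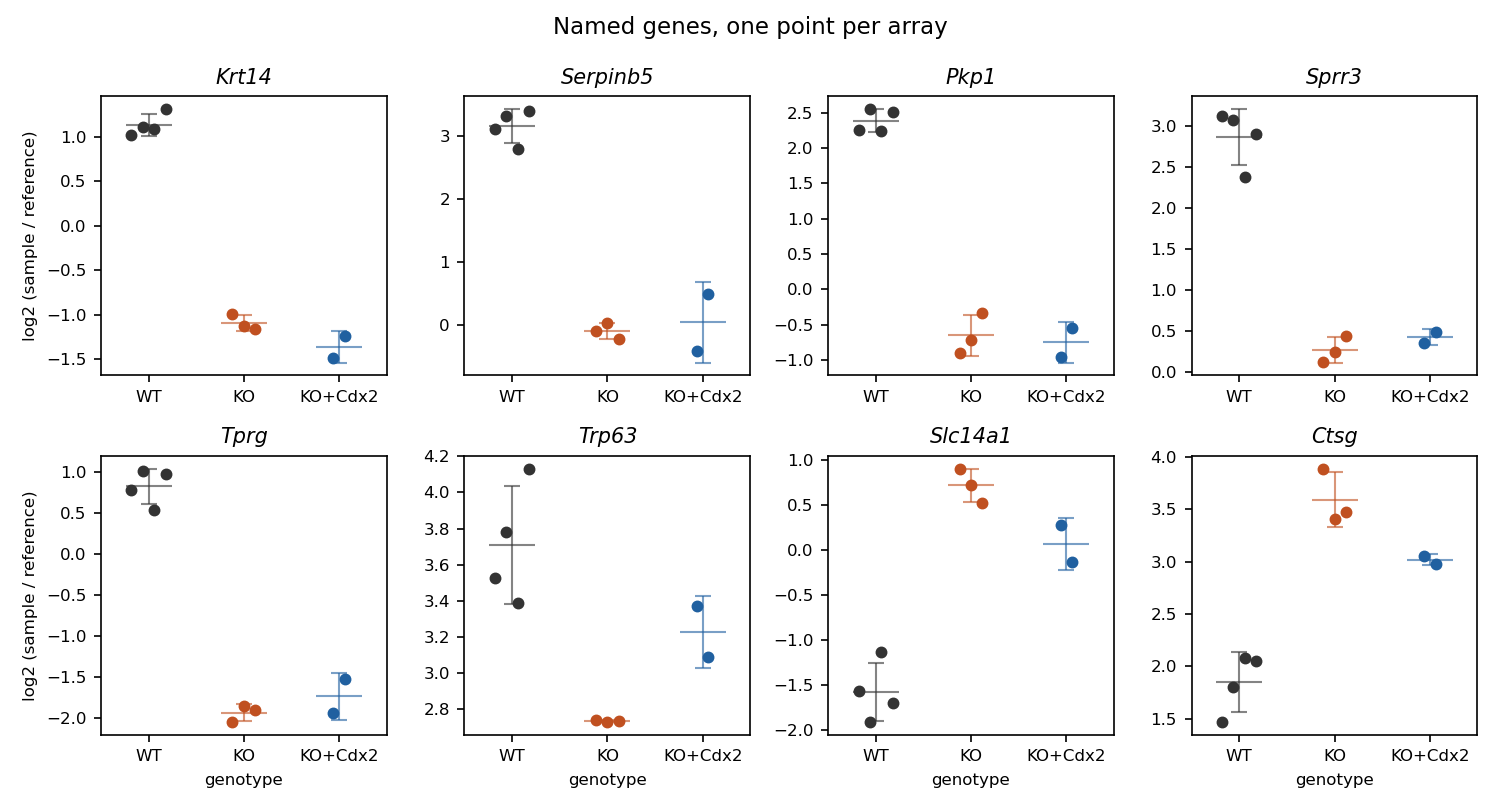
Log2 ratio of sample (Cy5) over reference (Cy3) on the vertical axis for 8 named genes, 1 point per array, for wild type (WT), p63 knockout (KO) and p63 knockout with Cdx2 transgene (KO+Cdx2), with bars at the mean ± SD. Krt14 lay at 1.13 ± 0.13 in wild type, -1.09 ± 0.09 in the knockout and -1.36 ± 0.18 in the knockout with Cdx2.

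For some genes the sample channel changed more than the log ratio, and the reference channel of the same probes moved in the same direction. Across genes, the knockout minus wild type differences of both channels correlated at r = 0.761 (genes are not independent replicates). For Serpinb5 the sample channel fell 31.9-fold and the reference channel differed by -1.53, and for Lypd3 the sample channel fell 45.7-fold and the reference channel differed by -3.09. In the sample channel alone limma called 440 genes, 181 higher and 259 lower, among them 68 of the 74, all in the same direction, while 54 of the 440 had a log ratio of the opposite sign. Krt5 and Krt15, keratins of basal cells picked after their values were seen, did not pass as ratios, at -1.48 (SE 0.47; limma, adjusted p = 0.434) and -0.36 (SE 0.10; adjusted p = 0.351). Their sample signals fell by 6.61 and 2.54 (limma, adjusted p = 0.0108 and 1.1e-04).

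Of the gene lists fixed beforehand, 10 of 28 shifted between knockout and wild type by camera with its preset correlation, 4 up and 6 down. Of the 40 measured suprabasal and cornified envelope genes, 13 fell, 0 rose and 27 did not pass, and 25 fell when adjusted over the list alone. The list median was -0.79, and besides Sprr3, Krt6b and Scel the members that fell included the esophageal keratin Krt4 (-0.94), Krt6a (-1.88) and the water channel Aqp3 (-1.97). Its shift had a camera adjusted p of 4.4e-33 and an adjusted p = 0.0744 with an estimated correlation. Of the 25 basal layer genes 4 fell, 0 rose and 21 did not pass, with 11 falling when adjusted over the list alone. The 4 were Krt14, the basement membrane collagen Col17a1 (-1.38), Perp (-1.97) and the ligand Wnt10a (-1.39). The 21 included Krt5 and Krt15, which fell in the sample channel alone, so not passing as a ratio does not show that a gene was unchanged. This list had a camera adjusted p of 1.6e-15 and an adjusted p = 0.0744 with an estimated correlation. Of the 12 desmosome genes 4 fell, 0 rose and 8 did not pass, with 8 falling when adjusted over the list alone. Pkp1, Perp, Pkp3 (-0.89) and Ppl (-1.02) were those 4, and the list had a camera adjusted p of 6.5e-15 and an adjusted p = 0.0888 with an estimated correlation. Of the 14 hemidesmosome and basement membrane genes 2 fell, Col7a1 (-1.71) and Col17a1, and 12 did not pass, with 3 falling when adjusted over the list alone. Camera gave this list an adjusted p of 0.00173, and an adjusted p = 0.497 with an estimated correlation. By fry, the suprabasal, basal and desmosome lists moved down (adjusted p = 0.00461 each), and these were the only 3 of 28 lists it called.

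The remaining camera shifts rested on no gene that passed over all genes. The 20 simple epithelium genes (median -0.12) and the 20 smooth muscle genes (median -0.16) shifted down, with 0 passing members each. Their adjusted p was 0.0101 and 1.7e-04 by camera, and adjusted p = 0.916 and 0.392 with an estimated correlation. The 47 multiciliated cell genes (median 0.23), 19 enteroendocrine genes (median 0.35), 34 immune cell genes (median 0.27) and 24 enteric neuron and glia genes (median 0.14) shifted up, again with 0 passing members each. With an estimated correlation these 4 had an adjusted p = 0.916, 0.517, 0.765 and 0.916. Of these 6 lists only smooth muscle was called in all 9 fits that left out 1 array. The simple epithelium call was lost without wild type replicate 1 or 4 or knockout replicate 1, the multiciliated call without wild type replicate 1 or 3 or knockout replicate 3, the enteroendocrine call without wild type replicate 2, the immune call without knockout replicate 1, and the enteric neuron call in 5 of the fits, without knockout replicate 1 among them. Median sample signals stood apart from the rest of the group on several of these arrays. They were 12.29 for simple epithelium in wild type replicate 1 (11.59 to 11.85 in the others), 7.47 for enteroendocrine genes in wild type replicate 2 (8.03 to 8.63), 12.08 for multiciliated genes in knockout replicate 3 (11.01 and 11.27) and 11.17 for enteric neuron genes in knockout replicate 1 (9.74 and 10.42).

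Adjusted over the list alone, 1 enteroendocrine gene was higher and 1 simple epithelium gene was lower. Pcsk1, a hormone processing enzyme of the enteroendocrine list, stood at 1.40 (SE 0.24; limma, adjusted p = 0.0734). The other 18 lists had camera adjusted p from 0.0935 to 0.851. Among them, the Wnt ligands Wnt10a and Wnt4 (-1.22) fell, 2 of 27 Wnt pathway genes, and 25 did not pass. Psca of the gastric list (-1.66) and the transcription factor Klf5 (-0.59) fell, each alone among 21 members, and Perp was the 1 of 24 p53 targets that fell.

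Leaving out 1 array moved the count of 74 genes by over 1.5 times in 8 of the 9 fits. It was 27, 121 and 44 without wild type replicate 2, 3 and 4, then 33, 22 and 26 without knockout replicate 1, 2 and 3, and 115 without either Cdx2 array. Of 27 named gene calls 12 held in all 9 such fits, among them Serpinb5, Pkp1, Krt14, Krt6b, Sprr3, Lypd3, Tprg, Wnt10a and Slc14a1, while Clec1b passed in 1, Gad1 in 2 and Scel, Ascl3 and Klf5 in 3 of them. The list count of 10 was reached or passed in 24 of 35 splits of these 7 arrays.

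The comparison of the knockout with Cdx2 (n = 2) and the knockout (n = 3) asked what the transgene adds in the absence of p63. Krt14 differed by -0.27 (SE 0.12; limma, adjusted p = 0.445), Pkp1 by -0.10 (SE 0.19; adjusted p = 0.879) and Serpinb5 by 0.14 (SE 0.27; adjusted p = 0.873). Ccne2, a cyclin of the G1 to S transition, had the lowest p of the cell cycle list, at 0.99 (SE 0.21; limma, adjusted p = 0.362). Aqp3 stood at -1.13 (SE 0.24; limma, adjusted p = 0.362). No gene passed. limma called 0 of 22626 genes, with 2590 at an unadjusted p under 0.05 against 1131 by chance and a lowest adjusted p of 0.214. It called 54 genes in the sample channel alone, 11 higher and 43 lower, of which 16 had a log ratio of the opposite sign, 4 from the scanner software's processed signals and from the authors' value table, 1 with a trended and robust prior, 36 without Cdx2 replicate 1 and 11 without Cdx2 replicate 2. In simulated data with these groups, 59.7% of genes changed by 1 on the log2 scale were called. That simulation drew the noise of each gene independently and changed 200 genes, which makes the adjusted threshold easier to reach than with 0 calls. The share is therefore no measure of what could be called here.

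Camera shifted 9 of 28 lists here, 3 up and 6 down, and every one of the 9 had an adjusted p = 0.840 with an estimated correlation and was not called by fry. The 36 cell cycle genes had a median of 0.63, with a camera adjusted p of 1.0e-19. None of them passed over all genes, and 2 were higher when adjusted over the list alone. The 52 intestinal epithelium genes, the list nearest to the known role of Cdx2, had a median of 0.09 with 0 passing members, both over all genes and adjusted over the list alone (camera adjusted p = 0.0369). Their median sample signal was 7.75 in Cdx2 replicate 1, within the knockout range of 7.67 to 7.87, and 8.10 in Cdx2 replicate 2. The 22 erythroid genes had a median of 0.39. The shifts down were of secretory and mucous (median -0.40), multiciliated (-0.22), fibroblast (-0.34), immune (-0.19), enteric neuron and glia (-0.30) and adipocyte genes (-0.37), with 3 fibroblast genes lower when adjusted over the list alone. The adipocyte median of the sample channel was 13.55 in knockout replicate 1, against 10.68 and 10.78 in the other knockouts and 10.15 and 10.87 with Cdx2. Without knockout replicate 1 camera no longer called the adipocyte and immune lists, and the intestinal call was lost in 4 of the 9 fits that left out 1 array. The other 19 lists had camera adjusted p from 0.0512 to 0.758. Without Cdx2 replicate 1 camera called 3 lists, and 2 of the 9 were among them. The airway genes Scgb3a1 and Muc5b, picked after their values were seen, were far lower in that replicate, with log2 sample signals of 11.11 and 7.84 against 18.41 and 14.88 in Cdx2 replicate 2.

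The knockout with Cdx2 (n = 2) against wild type (n = 4) asked for the joint change of both alterations. Ly6d, a surface protein of squamous epithelia, fell by 3.64 (SE 0.55) on the log2 scale, a fold of 12.5, with a range from -4.77 to -2.50 when 1 array was left out and the call lost in 4 of 9 such fits. Cysrt1 fell by 3.37 (SE 0.40), Pkp1 by 3.14 (SE 0.19), Serpinb5 by 3.12 (SE 0.25), Aqp3 by 3.11 (SE 0.23) and Krt14 by 2.49 (SE 0.11). Slc14a1 rose by 1.65 (SE 0.22) and nonagouti (a) by 1.22 (SE 0.14). In limma, 318 of 22626 genes changed, 98 higher and 220 lower, 90 of them at least 2-fold. There were 4097 genes at an unadjusted p under 0.05, against 1131 by chance.

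The other genes that fell most were Lypd3 by 2.90, the uroplakin Upk1b by 2.80 and Tprg by 2.55. Ms4a3 and Ctsg rose by 1.37 and 1.17. The other 6 of the 10 largest rises were near 1, namely Itgb3bp (1.07), Snx6 (1.06), Fancg (1.02), Rnaseh2b (1.01), Smc4 (1.00) and Eogt (0.98). Itgb3bp is a centromere protein, Smc4 a condensin subunit, and Fancg and Rnaseh2b act in DNA repair and in the removal of RNA from DNA. The limma adjusted p of these named genes was at most 0.0438. In the sample channel alone limma called 673 genes, 246 higher and 427 lower, and 264 of the 318 were among them, all in the same direction.

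Camera shifted 10 of 28 lists, 2 up and 8 down, of which fry called 4, the basal, suprabasal, desmosome and hemidesmosome lists (adjusted p = 0.00351 for the first 3 and 0.0327 for the last). Of the 40 suprabasal genes 16 fell and 24 did not pass, and 26 fell and 1 rose when adjusted over the list alone (camera adjusted p = 1.5e-18). Beside Ly6d and Aqp3 these included Krt13 (-1.46), the keratin pair partner of Krt4, and Ecm1 (-1.83). The fall of Krt13 was not particular to this group. In the knockout its ratio stood at -0.89 (SE 0.18; limma, adjusted p = 0.143). Its sample signal fell by 2.96 there and by 3.63 here (limma, adjusted p = 0.00122 each). Between the knockout with Cdx2 and the knockout its ratio differed by -0.57 (SE 0.21; limma, adjusted p = 0.401). Of the 25 basal genes 6 fell and 19 did not pass, with 12 falling when adjusted over the list alone (camera adjusted p = 1.1e-09), among them the integrin Itgb4 (-1.35). Of the 12 desmosome genes 5 fell and 7 did not pass, with 9 falling when adjusted over the list alone (camera adjusted p = 3.3e-09). These 3 lists had an adjusted p = 0.257 with an estimated correlation. Of the 14 hemidesmosome genes 3 fell and 11 did not pass, with 4 falling when adjusted over the list alone, namely Itgb4, Col17a1 (-1.83) and Col7a1 (-2.41) over all genes. That list had a camera adjusted p of 7.1e-04 and an adjusted p = 0.439 with an estimated correlation.

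The 36 cell cycle genes had a median of 0.64 against wild type (camera adjusted p = 1.3e-14; adjusted p = 0.577 with an estimated correlation). None passed over all genes and 26 rose when adjusted over the list alone. Pcna, a DNA replication clamp, had the lowest p, at 0.80 (SE 0.16; limma, adjusted p = 0.0549). The median cell cycle signal of the sample channel was 13.52 and 13.06 on the Cdx2 arrays, above each of the other 7 arrays, which lay between 12.02 and 12.89. Erythroid genes shifted up (median 0.56, 0 of 22 passing; adjusted p = 0.728 with an estimated correlation). Over the 9 arrays the medians of the cell cycle and erythroid lists moved together, with r = 0.884, and with r = 0.879 for the deviations from the group means, a comparison picked after the values were seen. The erythroid median was 11.79 in Cdx2 replicate 1 and 10.52 in replicate 2, which lay below wild type replicate 1 and 3 (10.73 and 11.21), and the call was lost without Cdx2 replicate 1.

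The other shifts down had passing members in 2 lists. Pmaip1 (-0.97) and Perp fell among 24 p53 targets, and Gsn (-1.08) and Col6a1 (-0.69) among 27 fibroblast genes. With an estimated correlation these lists had an adjusted p = 0.455 and 0.627, and both calls were lost without Cdx2 replicate 1, where the fibroblast median was 14.15 against 14.74 in replicate 2 and 14.36 to 14.91 in wild type. The p53 target call was also lost without wild type replicate 3. The secretory (median -0.32) and smooth muscle lists (median -0.32) had 0 passing members and an adjusted p = 0.842 and 0.439 with an estimated correlation, and the secretory call was lost in 7 of the 9 fits that left out 1 array. Smooth muscle had 4 genes falling when adjusted over the list alone. The other 18 lists had camera adjusted p from 0.0731 to 0.904. In them Wnt10a (-1.88), Wnt6 (-1.80), Wnt4 (-1.45), Psca (-2.48), Klf5 (-0.91), Elf3 (-1.20), Hoxd8 (-1.26) and the thyroid factor Foxe1 (-1.53) fell. Foxe1 was not well above background on either Cdx2 array, and wild type was at least 4.64-fold above that bound in the sample channel. With 1 array left out, Elf3 and Col6a1 passed in 1 of 9 fits, Hoxd8 and Foxe1 in 2, Wnt6 and Pmaip1 in 3 and Gsn in 4, and Hoxd8 ranged from -1.65 to -0.86 and Wnt6 from -2.25 to -1.35. A1cf, an RNA editing factor, had the lowest p of the 52 intestinal genes, none of which passed, at 1.53 (SE 0.31; limma, adjusted p = 0.0586).

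The count of 318 was 151, 58 and 59 without wild type replicate 1, 2 and 4, 134 and 92 without knockout replicate 2 and 3, and 188 and 199 without Cdx2 replicate 1 and 2. Of 33 named gene calls 15 held in all 9 fits, among them Pkp1, Serpinb5, Aqp3, Krt14, Lypd3, Tprg, Upk1b and Fancg, while Ms4a3 passed in 1 and Ctsg and Rnaseh2b in 3 of them.

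Both comparisons with wild type were then set side by side. Of the 74 genes that changed in the knockout, 66 (89.2%) also changed in the knockout with Cdx2, 7 higher and 59 lower, and 0 moved in opposite directions. Independent lists of these sizes would share 0.0563 higher and 0.593 lower genes. The 61 genes that fell had a median of -1.22 in the knockout and -1.46 in the knockout with Cdx2, with 46 of 61 further down there. No single gene passed between these groups, and the Cdx2 arrays differed. The median sample signal of the suprabasal list was 8.24 in Cdx2 replicate 1 and 10.13 in replicate 2, against 8.95 to 9.60 in the knockout. For the basal list it was 11.06 and 11.24, against 11.18 to 11.39. A further squamous loss with Cdx2 was therefore not shown. Of the 13 genes that rose 12 had a smaller change in the knockout with Cdx2, which their selection in the knockout favours by itself. Across genes the log2 differences correlated at r = 0.591, against 0.380 in simulated unchanged groups with the same wild type arrays, with a covariance of 0.0503 against 0.0147. The difference of the covariances, 0.0356, estimates the shared effect plus any effect of the wild type slide, which the simulations left out. With the wild type arrays split into 2 sets of 2, over 6 assignments, r was 0.296 on average (0.122 to 0.427) and the shared genes 12 to 24, of 19 to 49 called in the knockout and 17 to 115 with Cdx2. The covariance was then 0.0303 on average (0.0149 to 0.0401). Such a split leaves an effect of the wild type slide in both comparisons. The 66 became 23, 101 and 32 without wild type replicate 2, 3 and 4, and 30, 18 and 22 without knockout replicate 1, 2 and 3.

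Genes of organs next to the esophagus differed between arrays, within and between groups, and these were picked after their values were seen. Pga5, a pepsinogen, had a log2 sample signal of 18.82 in wild type replicate 1 and 7.08 to 9.64 on the other arrays. The thyroid gene Tg was at 17.92 and 17.24 in wild type replicate 3 and 4 and at 8.28 and 8.76 in replicate 1 and 2. In Cdx2 replicate 2, Krt5 was at 12.37 and the thymus genes Rag1 and Prss16 at 13.31 and 13.98, against 7.79, 6.92 and 8.07 in Cdx2 replicate 1. In knockout replicate 1, 2 and 3 Rag1 was at 9.52, 10.43 and 10.37, Prss16 at 8.40, 12.01 and 11.22 and Krt5 at 8.23, 9.70 and 8.99, while in wild type Rag1 was at 7.05 to 8.09 and Prss16 at 7.50 to 8.03. Ucp1, the gene of brown fat, was at 16.07 in knockout replicate 1 and at most 8.80 elsewhere.

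**Figure D2:**
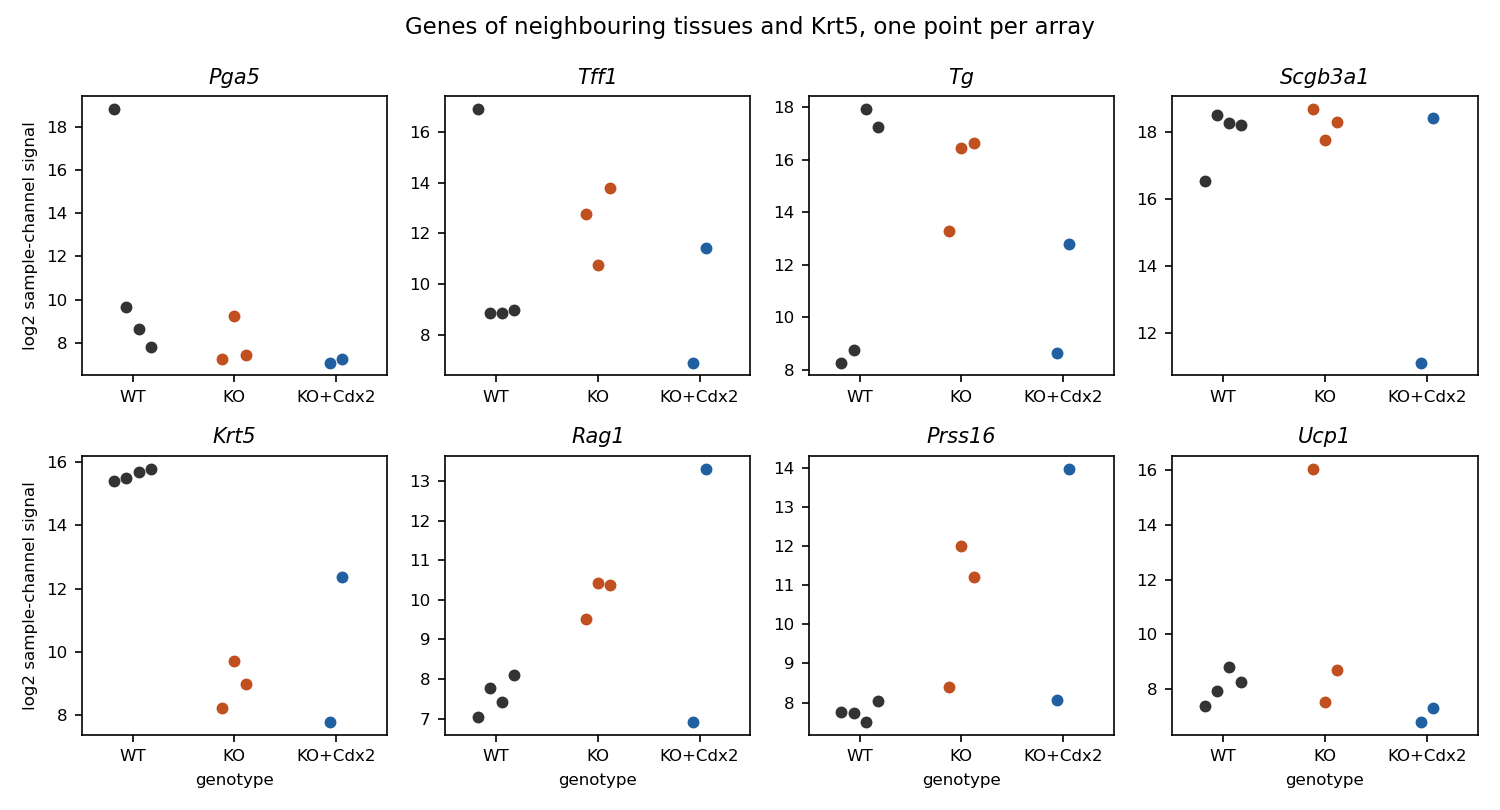
Log2 sample-channel signal on the vertical axis for 7 genes of neighbouring tissues and Krt5, 1 point per array, for wild type (WT), p63 knockout (KO) and p63 knockout with Cdx2 transgene (KO+Cdx2). Single arrays stand apart within a group, as for Pga5 at 18.82 in wild type replicate 1 and Scgb3a1 at 11.11 in Cdx2 replicate 1.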

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

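Of the tests in this part, those of a fixed share of light, of a whole slide, of stomach tissue and of a wrong label were chosen after the result was seen, and the others were written before their values were known. In the 4 wild type arrays, 2 of 88 genes had 1 array far from the other 3 by Dixon's test, while chance alone gives 4.40 (about 1 in 20). These were named genes, largely chosen for passing or for the lowest p, which favours a tight wild type group. The low count therefore does not show that no wild type array stood apart. Chga, a granule protein of endocrine cells, had a log2 ratio of 2.57 in wild type replicate 1, against 3.38 to 3.53 on the others. Col7a1 was at 1.26 in wild type replicate 1, against 1.63 to 1.65 on the others. Of the 35 splits of the wild type and knockout arrays into 4 and 3, only 1, the real one, called 74 genes or more, and the highest other called 6. This argues against chance for the gene count but does not exclude it, since 1 in 35 is the smallest share the splits allow. Each other split also mixed both genotypes in a group, which widens the spread and lowers its count. The real split is also the split by slide. For the count of 10 shifted lists chance stays open, since 24 of 35 splits shifted as many and the highest other shifted 17. The splits counted lists and did not ask which lists shifted or how far, so they decide nothing about any single list.

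The reference RNA was common to all arrays, and yet its signal followed the sample, with r of 0.761, 0.672 and 0.697 across genes in the 3 comparisons. A fixed share of Cy5 light read in the Cy3 channel is argued against, because the share differed between probes, with a ratio of the 90th to the 10th percentile of 4.00 and a median share of 7.96% over 74 probes. Probe effects of a whole slide are argued against too, because the reference followed the sample between the arrays of the 1 slide with both Cdx2 samples, at a median share of 4.89%. The shares of 123 probes correlated between the wild type and the Cdx2 slide (Spearman 0.920, probes not independent), which is consistent with sample target read in the Cy3 channel at a yield of its own for each probe. What gave that yield stays open, and no biological explanation was tested.

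In wild type replicate 1, 13 of the 21 measured genes of the gastric list set before the data were examined were at least 4-fold above the mean of the other wild type arrays, with a median log2 excess of 3.78, which is consistent with stomach tissue in that sample. A list of 15 stomach genes added after the data were seen, tried first and then replaced as no independent evidence, gave 11. A wrong label is argued against, because 29 squamous genes lay 3.91% of the way from the other wild type arrays to the knockout (median). These genes were chosen in a fit that counted this array as wild type, and 28 genes chosen without it lay at 3.79%. No biological explanation was tested.

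Krt5 in replicate 2 of the knockout with Cdx2 lay above replicate 1 by 12.3% of the wild type signal. The median of 15 thymus genes was 1.73 higher on the log2 scale there than in replicate 1, a list written because other thymus genes, left out of it, had been seen high in replicate 2, and so weak evidence for thymus tissue and none that Krt5 came from it. The 28 other squamous genes had gained a median of 6.93% of the wild type signal in replicate 2 (quartiles 1.74% and 18.1%), with 10 at or above the share of Krt5. That median goes with squamous epithelium left there, but the basal keratins did not follow Krt5. The signal over background of Krt15 was 50494 in replicate 1 and 48963 in replicate 2. For Krt14 it was 108 and 159, against 1777 to 2670 in wild type. Thymus tissue and squamous epithelium both stay open, since neither test argued against its explanation. With 1 array on either side the design gave no biological explanation to test.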

How the results depend on the processing

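Batch could not be entered in any fit, because each genotype had its own slide and scan, so the planned block for slide and scan was not run. Leaving out 1 array at a time gave 22 to 121 genes for the knockout against wild type, 0 to 36 for the knockout with Cdx2 against the knockout, 58 to 371 for the knockout with Cdx2 against wild type, and 18 to 101 shared genes. The list counts were 9 to 13, 3 to 12 and 8 to 12 in the same order. Where 1 Cdx2 array remained, it was assumed to vary like the other groups. For the knockout against wild type (74 genes), the count was 183 with no background subtraction, 133 from the scanner software's processed signals and from the authors' table, 440 in the sample channel alone, 115 with only 2 groups in the fit, 208 with array weights and 47 at 2-fold or more. For the knockout with Cdx2 against the knockout (0 genes) it was 4 from the processed signals and the authors' table, 54 in the sample channel and 1 with a trended and robust prior. For the knockout with Cdx2 against wild type (318 genes) it was 803 with no background subtraction, 166 with an offset of 16, 163 with median centring, 673 in the sample channel, 50 with 2 groups only, 544 with a trended and robust prior and 90 at 2-fold or more. The 66 shared genes became 158 with no background subtraction, 114 from the processed signals and the authors' table, 211 in the sample channel, 31 with 2 groups only and 116 with array weights. Camera with an estimated correlation called 0 lists in each comparison, and fry called 3, 0 and 4. With alternatives chosen after seeing the data, scaled log ratios gave 91 genes for the knockout with Cdx2 against wild type, with 17 lists there and 4 against the knockout, and sex as a covariate gave 129 genes. Trp63 in the knockout with Cdx2 against wild type turned from -0.48 to 0.21 as the mean over its probes (limma, adjusted p = 0.582). That turn came from the dim probe at 25865388 to 25866165, which moved the other way. Its log2 ratios were 0.16 to 0.73 in wild type and 1.13 to 1.43 in the knockout with Cdx2. The cause was not tested for any of the other changes. Aquantile scaling leaves log ratios as they are and moved nothing. Of 71 single gene results, 37 kept their side of the threshold with scaled ratios, 57 with the authors' table, 60 in the sample channel and 41 without wild type replicate 2 or 4. The replicate numbers were not taken to pair the arrays. Deviations of the same number correlated from -0.0612 to 0.183 between wild type and knockout (-0.197 to 0.193 for different numbers). Between wild type and the knockout with Cdx2 they correlated at 0.0686 and 0.188 (-0.188 to 0.0959 for different numbers). Between the knockout and the knockout with Cdx2 they correlated at -0.134 and -0.0314 (-0.0943 to 0.134 for different numbers). With 2 Cdx2 arrays, the deviations of one are those of the other with the sign turned. Where Cdx2 arrays enter, the values for different numbers are therefore no independent comparison. With the number as a replicate block limma called 9, 0 and 8 genes, 8 of them shared, 22 of the 71 gene results kept their side, and camera called 10, 13 and 9 lists. The signal stood well above background, with local background medians of 43 to 53 against sample medians of 309 to 472, and what limited the precision was not tested.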

Other observations

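This part gives values and no tests chosen for them, and its genes, as well as the lists for liver, pancreas and thymus, were picked after the data were seen. The fetal liver genes Alb and Afp were bright on all 9 arrays, with log2 sample signals from 15.59 to 18.60 and from 16.64 to 18.72. The liver list had medians from 11.26 to 15.03 per array. The cartilage list was highest in wild type replicate 3, at 12.96, where Ucma, a gene of growth plate cartilage, was at 15.74. The adipocyte list was highest in knockout replicate 1, at 13.55, and the exocrine pancreas list was at 11.33 there, against 7.84 to 9.14 on the other arrays. The thymus list was at 10.14 in Cdx2 replicate 2, against 7.98 to 8.78 elsewhere. In none of these added lists did a gene pass over all genes in any comparison, while 2 thymus genes were higher in the knockout with Cdx2 than in wild type when adjusted over the list alone, and the medians of the knockout minus wild type differences were 0.13 for liver, 0.67 for pancreas and 0.21 for thymus.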
